A study of Rattus norvegicus with 12 samples.

How the data were processed

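Kidney RNA from 12 male rats (strains S, R, SHR and WKY, 3 rats each) was measured on 1-colour rat circRNA arrays, 1 array per rat. Per the labels' protocols, rats were weaned at 28 to 30 days onto the low-salt diet, total RNA was treated with RNase R to enrich circRNAs, and random priming gave Cy3-labelled cRNA. Per the file headers, the scanner images were read with Agilent Feature Extraction 11.0.1.1, which gave each spot a background-subtracted, detrended signal intensity that is not normalized between arrays. The submitters' processing notes also name limma without saying how it was used. The deposited value table holds log2 values of 12846 circRNA probes. Its columns have nearly the same distribution, with medians between 6.70 and 6.75, and each ranks its probes like the raw median intensity of its own array (Spearman's rho of at least 0.995, with all 12 columns matching their own array best). How its values were centred and filtered is unknown. It has 1 channel and so no ratio direction. It was used as an alternative only.

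The scanner intensities were taken to log2, and the 75th percentile over the circRNA probes was subtracted from each array. Control spots were left out, 40 circRNA spots with an outlier flag were treated as missing, and no circRNA spot was saturated. A circRNA probe was tested if it was well above background, by the Feature Extraction flag, on all 3 arrays of at least 1 strain, and had at least 2 values without a flag in every strain. This kept 12438 of 14145 probes, with 1706 left out as too dim and 1 for missing spots. Each circRNA probe has 1 spot. The spots of each of 82 other probes were averaged, 10 spots for each of 62 probes with an mRNA accession and 20 for each of 20 probes with none.

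One linear model with a mean per strain was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom). Contrasts were S vs R, SHR vs WKY, S vs SHR, R vs WKY and the difference between S minus R and SHR minus WKY. The first 3 contrasts together gave the moderated F for any strain. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. The samples, circRNA tests, alternatives and naming rule were chosen before the data were examined, and the tests of mRNA probes after. Where a probe was not well above background on any array of a strain and was on all arrays of the other, its fold is a lower bound. The bound sets the brighter strain's mean log2 value against the dimmer strain's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. A difference between S minus R and SHR minus WKY is given without a size where a strain had no array well above background.

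The naming rule gave, per contrast, at most 2 circRNAs that rose and 2 that fell, those with the largest log2 fold change among called circRNAs whose compared strains did not overlap. Any circRNA called in both S vs R and SHR vs WKY was added. The files used here do not pair circRNA probes with host genes, positions or classes. So 14 host gene lists and the tests of position and class, with their 3 alternatives, were not run. The mRNA probes were named through unversioned accessions in the RefSeq gene table of the assembly GRCr8. Of the 62 probes with an accession 39 matched 1 gene each (38 genes), and 23 matched none. Of these 39, 35 were above background, by more than 50% of their spots, on all arrays of a strain and were fitted apart from the circRNAs. The other 4 (Fgf2, Lhcgr, Gdnf and P2rx2) were above background on no array. The mRNA probes belong to 3 of the 14 lists (proximal tubule, mitochondrial fuel oxidation and leukocytes) with 1 gene each, so these lists have values and no test. The other 11 lists have no value.

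Scan and position data in the file headers put the arrays on 2 slides. Slide 1 held S, R and WKY rats 1 and 2, and slide 2 held WKY rat 3 and SHR. Replicate numbers were checked for pairing by correlating the deviations of same-numbered rats from their strain means. Between-strain comparisons of single values used exact two-sided permutation tests, and overlaps Fisher's exact test.

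Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, normexp with quantile normalization, no filter on dim probes, a filter on all 12 arrays, the deposited log2 value table, the replicate number or the slide as a block, only the 2 compared strains, an intensity trend with robust variance, array weights, an unadjusted p under 0.05 with a fold of at least 1.5, an unmoderated test of the 2 strains, and leaving out each rat. Normexp used the median foreground signal because the files have no mean. Array weights were estimated gene by gene because the default did not converge. Added after seeing the data were the level of the mRNA probes as a covariate, the row of the slide as a block, fits within 1 slide, fits without a pair of rats, fits without a rat of the other strains, and every alternative for the mRNA probes.

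The number of arrays limits the precision of every value. The same code was tested on simulated data for S vs R, made from the means and spreads of 12413 real circRNAs with 200 of them changed. It recovered 18% of 2-fold, 56% of 4-fold, 94% of 8-fold and 96% of 16-fold changes, with 10 false among 142 calls, and made 0 calls when nothing was changed. The simulated errors were independent for each circRNA and array. So these rates leave out differences that many circRNAs share on an array, which the real arrays have, and say nothing about false calls from them.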

Results

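Circular RNAs (circRNAs), closed RNA rings formed when a downstream splice site joins an upstream one, were measured on 1-colour arrays in whole kidneys of 12 male rats from 4 inbred strains. The Dahl salt-sensitive strain (S) and the spontaneously hypertensive rat (SHR) are models of hypertension. The Dahl salt-resistant strain (R) and the Wistar Kyoto rat (WKY) are their usual normotensive counterparts. Each strain gave 3 rats, killed at 57 days of age on a 0.3% NaCl diet. The arrays held 14145 circRNA probes, and 12438 of them were bright enough to be tested. Values are log2 signals relative to the 75th percentile of the array. Host genes of the circRNA probes were not available here, so circRNAs are given by probe ID.

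The share of circRNA probes well above background was 81.4% ± 10.1 (SD, n = 3) in S, 88.7% ± 2.03 in R, 86.4% ± 2.67 in SHR and 86.6% ± 1.70 in WKY. The low mean and wide spread of S came from S rat 1, at 70.3%. S rats 2 and 3 stood at 90.1% and 83.9%. No pair of strains passed an exact two-sided permutation test over rats, with p = 0.3 for S vs R, 1 for SHR vs WKY, 0.5 for S vs SHR and 0.4 for R vs WKY. After Benjamini-Hochberg adjustment over these 4 tests the exact p was 0.667, 1, 0.667 and 0.667, and 3 rats against 3 cannot give a p under 0.1. S rat 1 was also the dimmest array, with a 75th percentile of 6.22 log2 units against 7.02 to 8.15 on the other 11.

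The first comparison, S vs R, asks which kidney circRNAs differ between the salt-sensitive strain and its resistant counterpart. A small set of circRNAs separated the strains by large amounts, 6 higher and 6 lower in S of 12438 tested (limma, Benjamini-Hochberg adjusted p under 0.05). ASCRPR008635 was 6.98-fold higher in S, at -0.48 ± 0.33 (SD, n = 3) against -3.28 ± 0.13 in R (log2 fold change 2.80, SE 0.31, adjusted p = 0.00324). ASCRPR007857 was higher by 2.97 log2 units (SE 0.40, adjusted p = 0.0118), at -1.87 ± 0.75 in S and -4.84 ± 0.46 in R, where it was well above background on 1 of 3 arrays. Several circRNAs were present in R and not well above background on any S array.

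ASCRPR010128 was at least 2.79-fold lower in S (adjusted p = 0.00137): it was well above background on 0 of 3 S arrays and on all 3 R arrays, at -2.60 ± 0.29. ASCRPR001672 was at least 4.10-fold lower in S (adjusted p = 0.0166), again on 0 of 3 S arrays, with -2.05 ± 0.74 in R. SHR and WKY showed both circRNAs at levels near those of R, with means of -2.33 and -2.47 for ASCRPR010128 and of -2.41 and -2.70 for ASCRPR001672. In all, 5 of the 6 circRNAs lower in S had this pattern of no S array and every R array well above background. All 12 called circRNAs had every S rat on one side of every R rat. Non-overlapping values were found for 1724 of the 12438 circRNAs (13.9%), where chance gives 10%, and 1791 had an unadjusted p under 0.05. This 10%, here and below, is what chance gives on average. CircRNAs that vary together on the arrays can move the share in 1 comparison far from it, and how far was not computed.

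The S vs R count was 0 with only these strains fitted, 2 with an unmoderated test and 3, all higher in S, with normexp, and it was 3525 without S rat 2, 58 without R rat 3, 6 without S rat 3 and 5 without R rat 2. All S and R arrays lay on slide 1, and the fit gave 10 circRNAs with slide as a block and 5 from slide 1 alone.

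**Figure D1:**
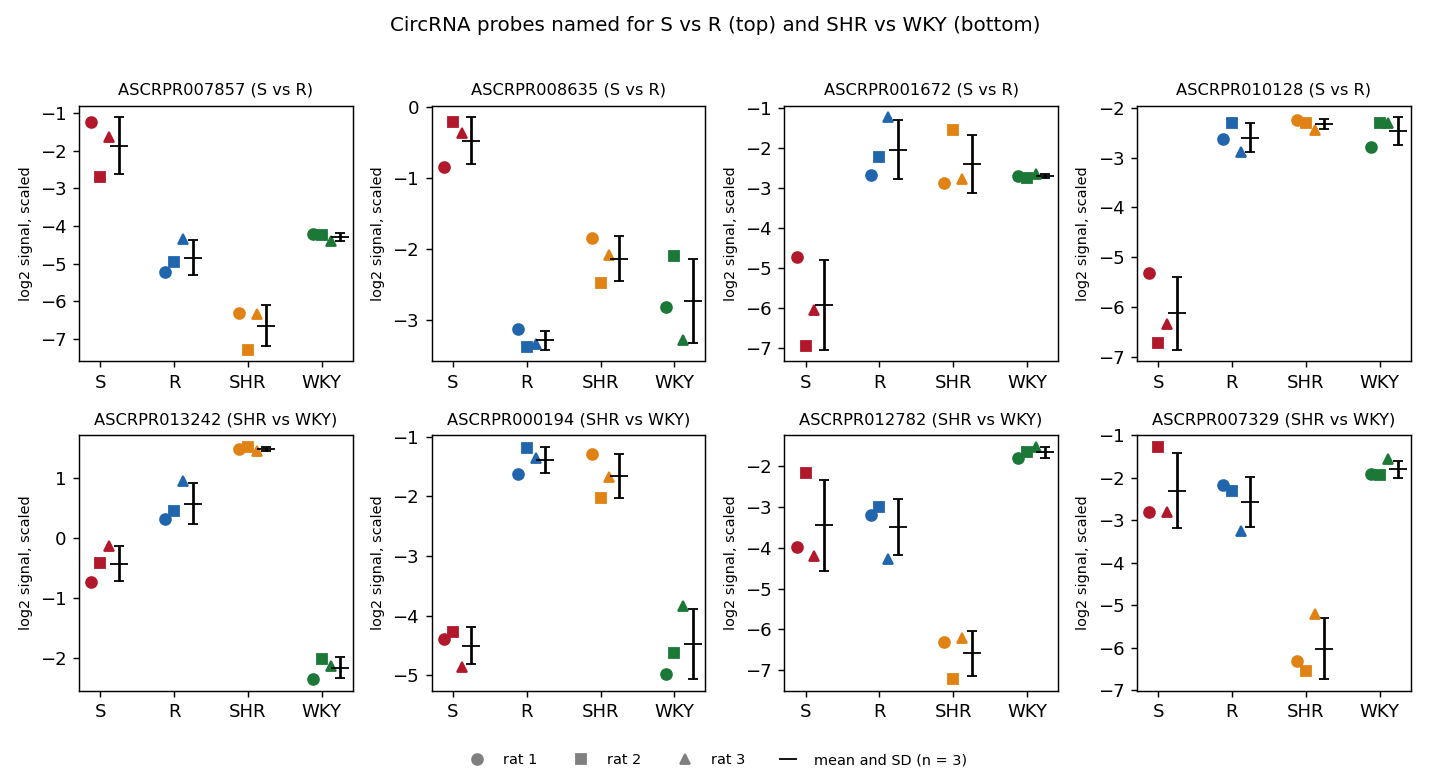
Scaled log2 signal of the 8 circRNA probes named for S vs R (top row) and SHR vs WKY (bottom row) in each rat, by strain; symbols mark rats 1, 2 and 3, and black bars give the mean and SD of 3 rats. In each panel the rats of the compared strains do not overlap; ASCRPR010128 is near -6.13 in S, not well above background there, and between means of -2.60 and -2.33 in the other strains.

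SHR vs WKY asks the same of the spontaneously hypertensive strain and its counterpart. Here 12 circRNAs were called, 4 higher and 8 lower in SHR. ASCRPR013242 was 12.5-fold higher in SHR, at 1.49 ± 0.036 (SD, n = 3) against -2.16 ± 0.17 in WKY (log2 fold change 3.64, SE 0.25, limma adjusted p = 6.15e-05). ASCRPR000194 was 7.01-fold higher, at -1.67 ± 0.37 against -4.48 ± 0.59 (log2 fold change 2.81, SE 0.32, adjusted p = 0.00346), and was well above background on 1 of 3 WKY arrays. Most of the circRNAs lower in SHR were not well above background on any SHR array.

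ASCRPR012782 was at least 6.44-fold lower in SHR (adjusted p = 0.00233) and ASCRPR007329 at least 5.86-fold lower (adjusted p = 0.00329). Their WKY means were -1.66 ± 0.13 and -1.80 ± 0.21, and 0 of 3 SHR arrays had either well above background. This held for 7 of the 8 circRNAs lower in SHR. All 12 had no overlap between the strains. Over all tested circRNAs 1157 (9.30%) had none, near the 10% that chance gives, and 245 had an unadjusted p under 0.05.

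With slide as a block 1 circRNA was called (median SE over the 12 of 0.55 against 0.38), and 0 were called from slide 2 alone, where WKY rat 3 was the lone WKY array and its spread was taken from SHR. SHR minus that array on slide 2 was 3.61 for ASCRPR013242 and 2.17 for ASCRPR000194, while ASCRPR012782 and ASCRPR007329 were at least 7.07-fold and 6.91-fold lower in SHR, and the count was 25 without S rat 2, 7 without WKY rat 3, 7 without SHR rat 1 and 1 each with normexp, with an unmoderated test and with the filter on all 12 arrays.

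The calls of S vs R and SHR vs WKY were then set against each other. A single circRNA was in both lists, ASCRPR000194, and it went opposite ways. It was lower in S than in R (log2 fold change -3.11, SE 0.32, limma adjusted p = 0.00235) and higher in SHR than in WKY, and was well above background on only 1 of 3 arrays in S and in WKY. Its levels were -4.51 ± 0.31 in S and -4.48 ± 0.59 in WKY against -1.39 ± 0.22 in R and -1.67 ± 0.37 in SHR. Finding 1 such circRNA, against 0.00193 from independent lists, gave an adjusted p of 0.00771 (Fisher's exact test, two-sided, over 4 direction pairs), but the lists shared 0 circRNAs with normexp, with normexp and quantile normalization and with the filter on all 12 arrays. With slide as a block ASCRPR000194 also lost its call in SHR vs WKY (log2 fold change 2.17, limma adjusted p = 0.284). The Fisher p treats circRNAs as independent, so it does not measure variation between rats. Across all circRNAs, which are not independent replicates, the log2 fold changes of the comparisons correlated with Pearson's r = 0.21 and Spearman's rho = 0.28, and 61.6% had the same sign. In the same direction 0 called circRNAs were shared, but lists this short had 0.00193 (higher in both) and 0.00386 (lower in both) expected, so that 0 tells nothing about sharing.

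The difference between S minus R and SHR minus WKY was tested for each circRNA, and 11 passed (limma, Benjamini-Hochberg adjusted p under 0.05), 8 with a positive and 3 with a negative difference. The named positive ones were ASCRPR007857 (adjusted p = 0.00269) and ASCRPR012782 (adjusted p = 0.0262), without a size because neither was well above background on any SHR array. The named negative ones were ASCRPR000194, at -5.92 (SE 0.46, adjusted p = 0.000139), and ASCRPR013242, at -4.64 (SE 0.35, adjusted p = 0.000139). ASCRPR007857 was 2.97 log2 units higher in S than in R, while its mean was -4.28 ± 0.11 in WKY. ASCRPR012782 lay at -3.45 ± 1.11 in S, well above background on 1 of 3 arrays, and -3.49 ± 0.69 in R. ASCRPR013242 lay at -0.42 ± 0.30 in S and 0.58 ± 0.34 in R. The count was 293 without S rat 2, 17 without S rat 1, and 3 to 7 without any one of S rat 3, R rats 1 and 2, WKY rats 1 to 3 and SHR rats 1 and 2. It was 2 with slide as a block, and ASCRPR012782 lost its call in 16 of 27 alternatives and ASCRPR007857 in 4. The difference for ASCRPR000194, well above background on 1 of 3 arrays in S and in WKY, ran from -6.25 to -1.59. It lost its call in 1 of 27, with normexp (-1.59, limma adjusted p = 0.692). For ASCRPR013242 the difference ran from -4.79 to -3.21, with 0 calls lost.

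S vs SHR set the hypertensive models against each other, and here many circRNAs were called, 1198 higher and 1134 lower in S of 12438 tested. The median size among the 2332 called was 1.55 log2 units. ASCRPR006961 was 77.1-fold higher in S, at 4.40 ± 0.22 (SD, n = 3) against -1.87 ± 1.89 in SHR (log2 fold change 6.27, SE 0.78, limma adjusted p = 0.00104). ASCRPR005925 was higher by 6.22 log2 units (SE 0.64, adjusted p = 0.000742), at 2.76 ± 0.36 against -3.46 ± 1.29, and was well above background on 1 of 3 SHR arrays. ASCRPR009827 was lower in S, at -2.13 ± 1.80 against 2.91 ± 1.01 in SHR (log2 fold change -5.05, SE 0.74, adjusted p = 0.0027).

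ASCRPR012603 was also lower in S, at -2.36 ± 3.03 against 2.26 ± 1.11 (log2 fold change -4.62, SE 1.18, adjusted p = 0.0297). For both circRNAs lower in S, 2 of 3 S arrays were well above background. Within SHR, rat 2 lay nearest to S on all 4: ASCRPR006961 was 0.27 in SHR rat 2 against -3.29 and -2.60 in rats 1 and 3, and ASCRPR009827 was 1.76 against 3.62 and 3.36. A further 21 called circRNAs were well above background on all SHR arrays and no S array, and 17 on all S arrays and no SHR array. Non-overlapping values were found for 3054 circRNAs (24.6%, against 10% by chance).

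All S arrays lay on slide 1 and all SHR arrays on slide 2, and with slide as a block, which only the WKY arrays on both slides tie together, the count was 0 because errors rose: over the 2332 circRNAs the median size went from 1.55 to 1.48 log2 units and the median SE from 0.40 to 0.76 (ASCRPR006961 from 6.27, SE 0.78, to 5.67, SE 1.45). Leaving out 1 rat gave 194 (SHR rat 1), 218 (SHR rat 3), 232 (S rat 3), 287 (S rat 1), 4276 (SHR rat 2) or 5612 (S rat 2), and outside the comparison 1383 (R rat 1), 1131 (R rat 2), 1357 (WKY rat 1) or 1121 (WKY rat 3). With only S and SHR fitted the count was 141, and with an unmoderated test 3. The fit of all strains shares 1 spread per circRNA, so its count also rests on the tighter R and WKY arrays. The median SD within a strain was 0.52 in S and 0.35 in SHR, against 0.26 in R and 0.27 in WKY.

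R vs WKY compared the normotensive counterparts, as a measure of strain divergence apart from hypertension. In it 105 circRNAs were called, 74 higher and 31 lower in R. ASCRPR006961, the circRNA with the largest log2 fold change among those named for S vs SHR, was also higher in R than in WKY, at 2.50 ± 1.07 (SD, n = 3) against -2.02 ± 0.57 (log2 fold change 4.53, SE 0.78, limma adjusted p = 0.0287). ASCRPR006672 was higher by 4.16 (SE 0.80, adjusted p = 0.038), at 3.13 ± 1.07 in R and -1.03 ± 0.47 in WKY. ASCRPR001904 was at least 5.46-fold lower in R (adjusted p = 0.0225), with 0 of 3 R arrays well above background and -2.43 ± 0.46 in WKY.

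ASCRPR009360 was lower in R, at -5.07 ± 1.28 against -1.52 ± 0.095 (log2 fold change -3.55, SE 0.67, adjusted p = 0.0375), with 1 of 3 R arrays well above background. S vs SHR and R vs WKY share no arrays, and their calls overlapped, but both run along the same difference in mRNA-probe signal (-0.67 to -0.23 in S and R, 0.76 to 2.52 in WKY and SHR rats 1 and 3), and S vs SHR also runs along the slides. With that signal as a covariate the counts were 109 and 5, and with slide as a block, which widened errors more than it changed sizes, 0 and 4. The mRNA-probe signal had no overlap between R and WKY, and between S and SHR only at SHR rat 2. A covariate so close to the comparison lowers counts whether or not linear RNA matters, so these counts cannot tell it from strain. Of the 74 circRNAs higher in R, 54 were also higher in S than in SHR, against 7.13 from independent lists (Fisher's exact test, two-sided, adjusted p = 1.55e-38). Of the 31 lower in R, 19 were lower in S, against 2.83 (adjusted p = 1.46e-12). These p-values treat circRNAs as independent, which they are not, and do not measure variation between rats. Both comparisons also share the spread of each circRNA, so the lists are not independent. In opposite directions 0 and 2 were shared. Across circRNAs the log2 fold changes correlated with Pearson's r = 0.76 and Spearman's rho = 0.75, and 5944 circRNAs (47.8%, against 10% by chance) had no overlap between R and WKY.

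The R vs WKY count was 1536 without SHR rat 2 and 572 without S rat 2. With only R and WKY fitted it was 2758, and with an unmoderated test 21. Leaving out a rat of R or WKY gave 38 (R rat 1), 4 (R rat 2), 19 (R rat 3), 9 (WKY rat 1), 11 (WKY rat 2) or 4 (WKY rat 3), and leaving out S rat 3 or SHR rat 3 gave 17 or 50. With slide as a block 4 were called, with a median size over the 105 of 2.35 log2 units against 2.44 and a median SE of 0.50 against 0.44, and 1 from slide 1 alone, which held all R arrays and WKY rats 1 and 2.

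Over all 4 strains together, 1748 circRNAs (14.1%) differed somewhere (limma moderated F over 3 independent contrasts, Benjamini-Hochberg adjusted p under 0.05). This count was 5855 without S rat 2, 3837 without SHR rat 2, 220 to 800 without any other single rat, and 92 with slide as a block. The first principal component of the circRNA signals held 62.3% of the variance and placed WKY rats 1 to 3 with SHR rats 1 and 3, apart from S and R. SHR rat 2 lay at -9.13 on it, next to R rat 2 at -12.2 and S rat 2 at -15.4. S rats 1 and 3 lay at -117 and -87.5, and R rat 3 at -51.6.

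**Figure D2:**
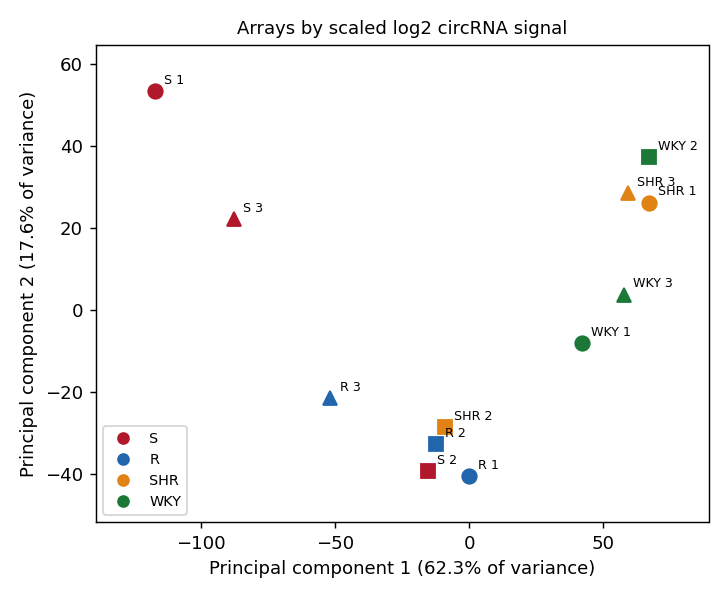
First principal component (62.3% of variance) against the second (17.6%) of the scaled log2 circRNA signals; each point is an array, coloured by strain, with a symbol per rat number. SHR rat 2 (-9.13 on the first component) lies with S rat 2 and R rats 1 and 2, away from SHR rats 1 and 3 (67.0 and 59.2).

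The same arrays carry probes to linear mRNAs, which RNase R, an exonuclease that digests linear RNA, was used to remove before labelling. Of these, 35 probes to 34 named genes were bright enough to test. In S vs SHR 15 were called, 14 lower and 1 higher in S, and in R vs WKY 16 were called, 15 lower and 1 higher in R (limma, Benjamini-Hochberg adjusted p under 0.05). Genes named here were chosen after their values were seen.

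Rplp1, a protein of the large ribosomal subunit, was at -0.77 ± 0.99 (SD, n = 3) in S and 0.40 ± 0.26 in R against 3.66 ± 3.02 in SHR and 4.88 ± 2.05 in WKY. Its log2 fold change was -4.44 in S vs SHR (adjusted p = 0.027) and -4.48 in R vs WKY (adjusted p = 0.0225). Ldha, a subunit of lactate dehydrogenase, had log2 fold changes of -3.20 (adjusted p = 0.0444) and -3.78 (adjusted p = 0.0225) on one probe, and of -0.996 (adjusted p = 0.141) and -1.80 (adjusted p = 0.0225) on the other. Pgk1, a glycolytic enzyme, had -2.75 (adjusted p = 0.0423) and -2.97 (adjusted p = 0.0232). B2m, the light chain of class I histocompatibility molecules, had -1.83 (adjusted p = 0.0444) and -2.45 (adjusted p = 0.0225). Hprt1, a purine salvage enzyme, had -2.54 (adjusted p = 0.027) and -2.69 (adjusted p = 0.0225). Cse1l, a nuclear export receptor, had -3.62 (adjusted p = 0.0193) and -3.60 (adjusted p = 0.0225). Rpl13a had -1.62 (adjusted p = 0.0853) and -2.37 (adjusted p = 0.0225). Other reference genes passed in neither: Actb had -0.62 (adjusted p = 0.203) and -1.01 (adjusted p = 0.0556), Gusb -1.09 (adjusted p = 0.161) and -0.80 (adjusted p = 0.289), and Hsp90ab1 0.62 (adjusted p = 0.161) and 0.95 (adjusted p = 0.0508).

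Ptk2b, a calcium-dependent tyrosine kinase, went the other way, with 3.79 (adjusted p = 0.00315) in S vs SHR and 1.74 (adjusted p = 0.0479) in R vs WKY. Cyp2e1, a cytochrome P450 and the proximal tubule gene among the named probes, was at -1.38 ± 0.11 in S, -0.98 ± 0.30 in R, 0.40 ± 2.01 in SHR and 0.96 ± 0.64 in WKY, and passed in no comparison. Sdha, a subunit of mitochondrial succinate dehydrogenase, had log2 fold changes of -0.39 (adjusted p = 0.625) and -1.86 (adjusted p = 0.0508) in S vs SHR and R vs WKY. Nlrp3, an inflammasome sensor of leukocytes, had 0.24 (adjusted p = 0.625) and 0.23 (adjusted p = 0.645). No mRNA probe was called in S vs R, where 2 had an unadjusted p under 0.05, or in SHR vs WKY, where 0 did, and an unmoderated test also called 0 in each.

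The mRNA signal did not follow strain within SHR and WKY. The mean of a custom set of 12 mRNA probes was 2.27 and 1.87 in SHR rats 1 and 3 but -0.56 in SHR rat 2, and 2.52 and 2.00 in WKY rats 2 and 3 but 0.76 in WKY rat 1. In S and R it lay between -0.67 and -0.23. By strain it was -0.60 ± 0.064 in S, -0.39 ± 0.16 in R, 1.19 ± 1.53 in SHR and 1.76 ± 0.91 in WKY (exact two-sided permutation p = 0.2 for S vs SHR and 0.1 for R vs WKY, both 0.267 after adjustment over 4 tests). With this mean as a covariate the circRNA counts were 109 for S vs SHR and 5 for R vs WKY, against 12 for S vs R and 10 for SHR vs WKY. The mean nearly follows the first pair of comparisons, so their lower counts cannot tell linear RNA from strain. The mRNA probe counts were 27 in S vs SHR and 23 in R vs WKY without SHR rat 2. In S vs SHR they fell to 1 without S rat 1, SHR rat 1 or SHR rat 3, 2 without S rat 3 and 9 without R rat 1. In R vs WKY they fell to 0 without R rat 2 or WKY rat 3, 2 without R rat 1 or WKY rat 2 and 10 without R rat 3. From slide 1 alone, which held all R arrays and WKY rats 1 and 2, 15 mRNA probes were called in R vs WKY, all lower in R. With slide as a block both counts were 0. Over the 15 called in S vs SHR the block moved the median size from 2.10 to 1.80 and the median SE from 0.67 to 1.28. Over the 16 in R vs WKY it moved them from 2.41 to 2.36 and from 0.69 to 0.81. Single genes in S vs SHR moved unequally. Ldha went from -3.20 to -1.68 on its called probe, Cse1l from -3.62 to -2.25, Rplp1 from -4.44 to -2.98 and Hprt1 from -2.54 to -2.30.

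**Figure D3:**
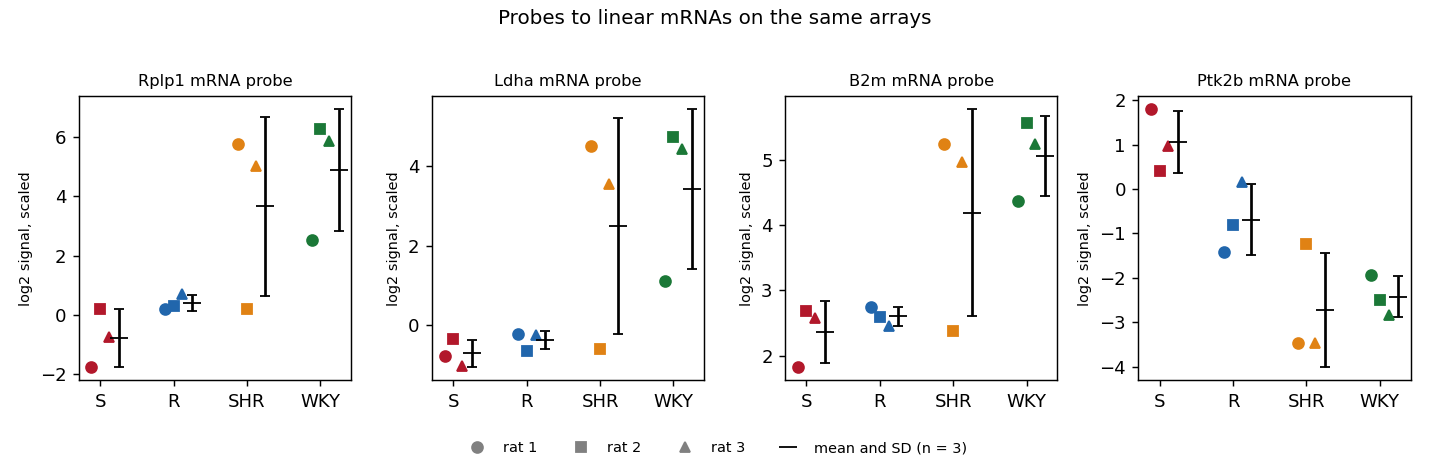
Scaled log2 signal of 4 mRNA probes (Rplp1, Ldha, B2m, Ptk2b) in each rat, by strain; symbols mark rats 1, 2 and 3, and black bars give the mean and SD of 3 rats. SHR rat 2 lies with S and R, away from SHR rats 1 and 3, for Rplp1 (0.20 against 5.77 and 5.01).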

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

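The tests of SHR rat 2, S rat 2 and the differences within WKY and R reported here were chosen after the results were seen; the counts over other splits of the rats were planned.

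A test of the difference between S minus R and SHR minus WKY called 11 circRNAs. The named negative ones were ASCRPR000194 (-5.92 log2 units, but -1.59 with normexp, with S and WKY each well above background on 1 of 3 arrays) and ASCRPR013242 (-4.64). The named positive ones, ASCRPR007857 (adjusted p = 0.00269) and ASCRPR012782 (adjusted p = 0.0262), have no size because no SHR array had them well above background, and they lost the call in 4 and 16 of 27 alternatives. Of 100 drawn splits of the 12 rats into 4 groups of 3, the real one included, 5 called as many, with up to 4440 calls in another split, so chance was not excluded for this count. For circRNAs that differed between any strains, 3 of 100 splits called as many as the real 1748, with a highest other of 4506, a share under 0.05. These splits took no account of the slide, so the share cannot tell strain from slide. The count was 92 with slide as a block and 24 with the mRNA level as a covariate.

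Probes that no comparison used also gave signal. Of the 20 probes without an accession, 4 were above background on all 12 arrays, and what they measure is unknown here.

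The 3-against-3 comparisons have 10 splits of 6 rats each, too few for a share under 0.05. For S vs R 2 of 10 splits called as many as the real 12, with 2944 in the other. For SHR vs WKY 1 of 10 did (real 12, highest other 0). For S vs SHR it was 2 of 10 (real 2332, highest other 2419), and for R vs WKY 1 of 10 (real 105, highest other 0). The 2944 calls set S rats 1 and 3 with R rat 3 against S rat 2 with R rats 1 and 2, and the 2419 calls set S rats 1 and 3 with SHR rat 2 against S rat 2 with SHR rats 1 and 3. Splits that call this many point to a structure among the arrays that crosses the strains.

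The S vs SHR differences moved with the signal of linear mRNA probes. Over all tested circRNAs SHR rat 2, low in mRNA signal, had Pearson correlations of at most 0.914 with SHR rats 1 and 3 and 0.929 with any array of its slide, but at least 0.961 with the R arrays on the other slide, which argues against the slide alone and, if its label is right, against the strain alone. With values raised to the background limit of each array, SHR rat 2 lay on the side of SHR rats 1 and 3 on 30 of 36 circRNAs (83.3%) that set these apart from WKY. It lay with S on 0 of 9 specific to S, and both counts argue against a WKY or S rat under its label. An R rat stays open. As measured, of 11 circRNAs that set SHR rats 1 and 3 apart from the other strains, SHR rat 2 lay beyond these on 9 (81.8%) and past the middle on 5. On raised values it lay beyond on 3 of 3 and past the middle on 0. ASCRPR013242 was 1.52 in SHR rat 2 and at most 0.96 in R. ASCRPR012782 and ASCRPR007329 were -7.21 and -6.54 in SHR rat 2, with R means of -3.49 and -2.58. Both were well above background on 0 of 3 SHR arrays and on all 3 R arrays. On these circRNAs SHR rat 2 lay with SHR, but it was among the arrays that picked them. ASCRPR000194, also named for SHR vs WKY, hardly separated SHR from R (means -1.67 and -1.39). Yet as measured SHR rat 2 lay with R on both of 2 circRNAs specific to R. R had 0 specific circRNAs with no array left out, so these could enter only where SHR rat 2 lay near R and say little about its label. Within WKY, rat 1 (mean mRNA-probe signal 0.76) minus rats 2 and 3 (2.52 and 2.00) had the sign of S minus SHR for 79.4% of the 2332 called circRNAs, against 63.4% of all, so uneven removal of linear RNA is a candidate explanation for part of the count. Strain and slide stay open for the rest, and some mRNA probes may also bind circRNAs of their gene, which was not tested.

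The S vs R count rose from 12 to 3525 without S rat 2. Over all tested circRNAs S rat 2 had a Pearson correlation of at most 0.906 with S rats 1 and 3 but at least 0.956 with R, which, if its label is right, argues against the strain alone, while leftover linear RNA stays open, since its mean over 12 mRNA probes differed from that of S rats 1 and 3 by 0.0707 log2 units but 35 single probes went both ways (-1.94 to 2.77). A wrong label for S rat 2 stays open: of 501 circRNAs that set S rats 1 and 3 over 1 log2 unit beyond the 9 arrays of other strains, S rat 2 lay beyond those 9 on the same side on 94 (18.8%) and past the middle of the gap on 38 (7.58%), and it lay with R on both of 2 circRNAs specific to R, with SHR on 0 of 5 and with WKY on 1 of 7. With S rat 2 included R had 0 specific circRNAs, so those 2 could enter only where S rat 2 lay near R and say little about its label. Against a wrong label, 17 circRNAs set S rats 1, 2 and 3 all apart, with at most 5 for any of 8 other arrays in place of S rat 2, but 172 for R rat 3. Also against it, 7 circRNAs were well above background on all 9 arrays of the other strains and on no S array. ASCRPR010128, not well above background on any S array, was -6.73 in S rat 2, with means of -2.60 in R, -2.33 in SHR and -2.47 in WKY. S rat 2 was among the arrays that picked these. Within R, rat 3 minus rats 1 and 2 had the sign of S minus R for 90.3% of the 3525, against 74.0% of all, so a difference between single kidneys or RNA samples that runs across S and R is a candidate explanation, and what it is (RNA quality, dissection or a trait of single rats) stays open.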

How the results depend on the processing

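Alternatives reported as added in the methods were chosen after seeing the data. No named circRNA changed direction in any alternative, but sizes moved: the log2 fold change of ASCRPR008635 in S vs R, 2.80 as reported, ran from 1.32 to 3.00, and that of ASCRPR013242 in SHR vs WKY, 3.64 as reported, from 2.46 to 3.78. The 4 named for S vs R kept their calls, by the test of each alternative, in 96 of 121 values and the 4 for SHR vs WKY in 102 of 121, and the calls lost were 2 for ASCRPR008635, 1 for ASCRPR013242 and 4 to 10 for each of the 6 others, which lie nearer background. For S vs SHR it was 101 of 117, for R vs WKY 74 of 122 and for the difference 88 of 109. The named mRNA probes changed direction in none of the alternatives run and kept their calls in 82 of 161 values for S vs SHR and 124 of 168 for R vs WKY. How far a signal stood over background limits what can be seen: median circRNA signals were 23.2 on S rat 1 and 49.0 to 98.5 on the other arrays, against an added offset of 50 in normexp. Except where a reason is given, the cause was not tested for the counts that follow.

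Normexp gave 3 circRNAs for S vs R, 1 for SHR vs WKY, 639 for S vs SHR, 62 for R vs WKY, 2 for the difference, 884 for any strain, 0 in the overlap and 1 mRNA probe for S vs SHR. Quantile normalization gave 20 for S vs R and 2 in the overlap, both in opposite directions. Normexp with quantile normalization gave 3 for SHR vs WKY, 3 for the difference, 0 in the overlap and 3 mRNA probes for S vs SHR. The filter on all 12 arrays, which removes circRNAs missing from a strain, gave 5 for S vs R, 1 for SHR vs WKY, 3 for the difference and 0 in the overlap. The deposited value table gave 6 for SHR vs WKY, 159 for R vs WKY and 3 for the difference.

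For S vs SHR the share of calls higher in S was 51.4% as reported, 61.6% with median scaling and 68.5% with normexp, a background correction. For S vs R and SHR vs WKY median scaling gave 53.8% and 27.3%, near the reported 50% and 33.3%. Normexp left 3 calls for S vs R and 1 for SHR vs WKY, all higher. With normexp and quantile normalization together 12 of 13 and 2 of 3 were higher. These calls are too few to read as a share. Quantile normalization without normexp gave 10 of 20 higher for S vs R and 5 of 16 for SHR vs WKY. Median scaling shifted the median over all circRNAs to 0.13 log2 units in S vs SHR, and normexp to 0.22 in S vs R and -0.12 in R vs WKY.

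Same-numbered rats showed no steady shared deviation (4 of 18 pairs of strains and numbers correlated over 0.1, range -0.54 to 0.52). Rats of different numbers were not compared in the same way, so this check cannot settle whether the number is a pairing. With the replicate block the counts were 7 for S vs R, 439 for S vs SHR, 7 for R vs WKY, 4 for the difference and 278 for any strain. Slide as a block gave 1 for SHR vs WKY, 0 for S vs SHR, 4 for R vs WKY, 2 for the difference, 92 for any strain, and 0 mRNA probes for S vs SHR and for R vs WKY. For R vs WKY slide 1 alone gave 15 mRNA probes, all lower in R. Row of the slide as a block gave 6 for S vs R, 5 for SHR vs WKY, 1373 for S vs SHR, 59 for R vs WKY, 6 for the difference and 621 for any strain. Slide 1 alone gave 5 for S vs R and 1 for R vs WKY, and slide 2 alone 0 for SHR vs WKY, each with fewer arrays.

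Only the compared strains gave 0 for S vs R, 141 for S vs SHR, 2758 for R vs WKY and 3 mRNA probes for S vs SHR. Trend with robust variance gave 19 for S vs R. Array weights, lowest for S rat 2 (0.15) and SHR rat 2 (0.20), gave 6537 for S vs R, 86 for SHR vs WKY, 8156 for S vs SHR, 5173 for R vs WKY, 3840 for the difference and 9874 for any strain. Unadjusted p under 0.05 with a fold of 1.5 gave 1734, 216, 4796 and 3099 for the 4 comparisons in the order S vs R, SHR vs WKY, S vs SHR and R vs WKY, 647 for the difference and 4665 for any strain. The unmoderated test gave 2, 1, 3 and 21 in that order, and 0 mRNA probes for S vs SHR. The mRNA level as a covariate, which lay apart between R and WKY and so takes up part of the strain difference, gave 109 for S vs SHR, 5 for R vs WKY and 24 for any strain.

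Without S rat 1 and SHR rat 2 together the counts were 19 for S vs R, 2285 for R vs WKY and 3120 for any strain. Without S rat 2 and SHR rat 2 together they were 4721 for S vs R, 21 for SHR vs WKY, 6650 for S vs SHR, 3157 for R vs WKY, 1028 for the difference and 7508 for any strain, with 5, 26 and 25 mRNA probes for S vs R, S vs SHR and R vs WKY. Leaving out 1 rat gave 5 (R rat 2) to 3525 (S rat 2) for S vs R, 7 (WKY rat 3, SHR rat 1) to 25 (S rat 2) for SHR vs WKY, 194 (SHR rat 1) to 5612 (S rat 2) for S vs SHR, 4 (R rat 2, WKY rat 3) to 1536 (SHR rat 2) for R vs WKY, 3 (WKY rat 3) to 293 (S rat 2) for the difference and 220 (S rat 3) to 5855 (S rat 2) for any strain. For mRNA probes it gave 0 to 1 for S vs R, 0 in every case for SHR vs WKY, 1 to 27 for S vs SHR and 0 to 23 for R vs WKY. The gene list alternatives were not run.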

Other observations

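In a count apart from the pairwise comparisons, a few circRNAs set all arrays of S, WKY or SHR apart from the rest, though none did with normexp. Of 12413 circRNAs with a value on every array, 17 had all 3 S arrays over 1 log2 unit beyond the other 9 arrays, 8 above and 9 below. For WKY there were 6 (4 above, 2 below), for SHR 5 (1 above, 4 below) and for R 0. Some of these gaps end at background, where the true level is unknown. With every value raised to the lowest signal among probes well above background on its array, the counts were 9 for S (7 above, 2 below), 2 for WKY (1 above, 1 below) and 0 for SHR and for R. Among all 220 trios of arrays, 3 had as many as S and 5 as many as WKY on these raised values, an exact one-sided p of 0.0136 and 0.0227, each 0.0455 after Benjamini-Hochberg adjustment over the 4 strains. For SHR and R the exact p was 1. Trios that cross strains included S rats 1 and 3 with R rat 3 (150 circRNAs) and WKY rat 2 with SHR rats 1 and 3 (17), and 213 of the 220 trios had none. As measured, with quantile normalization the counts were 16 for S, 0 for R, 7 for SHR and 7 for WKY. With median scaling they were 13, 0, 8 and 6, and with normexp 0 for every strain. These counts were chosen after the data were seen. The exact p treats all arrays as exchangeable and takes no account of slide or of differences that cross strains.

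On the raised values the circRNA with the widest such gap in S was ASCRPR005699, 1.26 log2 units above every other array, at 0.086 ± 0.13 (SD, n = 3) against means of -2.44 in R, -1.49 in SHR and -1.45 in WKY. In WKY it was ASCRPR013242, 1.28 below every other array, at -2.16 ± 0.17 against -0.42 in S, 0.58 in R and 1.49 in SHR. Both were well above background on all 12 arrays. Well above background on all 9 arrays of the other strains and on none of their own were 7 circRNAs in S, 2 in SHR, 3 in WKY and 0 in R. The opposite, well above background on all 3 arrays of 1 strain and on none of the other 9, was found for 2 circRNAs in S, 3 in R and 0 in SHR and WKY.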
